A study of Homo sapiens with 6 samples.

How the data were processed

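RNA was measured in 6 libraries of SNU449, an established human hepatocellular carcinoma cell line. Per the labels, cells were transfected 24 h after seeding with 100 nM of an siRNA against SF3B6 or a scrambled control siRNA and harvested 48 h later, and each library was made from 3 µg of total RNA by selection of polyadenylated RNA and sequenced on a DNBSEQ-T7. The labels give 3 libraries per siRNA, numbered 1 to 3 in each group. No label says that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Neither the siRNA sequences nor the number of siRNAs in the mixture is given in the sources used here.

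Reads were trimmed with Cutadapt and Trimmomatic, per the labels' protocols. Per the submitters' processing notes, the authors used STAR 2.7.3, RSEM 1.3.3 and DESeq2 with the hg38 genome; the gene annotation is not given in the sources used here. The deposited table holds a signal per gene and library: the authors' estimated counts divided by DESeq2 normalization factors, as the name of the deposited table says. In each library 31.5% to 34.4% of low values lay within 10% of whole multiples of its most frequent low value (0.946 to 1.44), so no single value of 1 read was established and whole reads could not be recovered, whether from fractional estimated counts or from factors that differed between genes. Count models were therefore not run, and the planned count-based alternatives were left out. The table had 19956 rows, nearly all protein-coding genes, of which 15541 were above 0 in at least 1 library; 6 symbols stood on 2 rows. Normalized totals were 11.85 to 12.52 M per library, higher in every knockdown library than in any control. The depth in reads is unknown.

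Values were transformed to log2(value + 1), and the 12135 genes with a mean of at least 10 over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (moderated variances with a trend on the mean, 2-sided, Benjamini-Hochberg adjustment, adjusted p threshold 0.05). Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Gene lists were compared with the other tested genes by limma's camera with a preset inter-gene correlation of 0.01 over 25 lists with at least 4 tested members, and also by camera with an estimated correlation. The fry test, which sets each list against no change and not against other genes, was run beside them. In simulated data built on these libraries, with 200 of 12135 genes changed, the same test recovered 93.9% of 2-fold rises, 72.7% of 2-fold falls, 67.6% of 1.5-fold rises and 20.6% of 1.25-fold rises, with 5 false calls among 115. Single measures of 3 against 3 libraries were compared by 2-sided exact permutation, for which 0.1 is the smallest p possible.

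The design, the gene lists and the rule for named genes were fixed before the data were examined. The rule took SF3B6, the 6 largest rises and the 6 largest falls among genes past the threshold with a mean of at least 100 and groups that did not overlap, the SF3b members, and up to 4 members of each list in order of adjusted p. Members outside that rule that are named because a count was 5 or fewer were chosen after their values were seen. Some genes that the rule selects are not reported here. Alternatives covered the pseudocount, the filter, 3 other scalings, the variance model, a replicate block, each library left out in turn and stricter thresholds.

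Gene positions, introns, transcript length, GC content and 3′ UTRs came from GENCODE release 29 on the hg38 genome (GRCh38), matched by symbol for 12021 of the 12135 tested genes (99.1%). Medians of lists were set against 10000 random lists in which each member was replaced by 1 of its 10 nearest genes in the stated features. All 16384 heptamers were counted in the 3′ UTRs of 11869 tested genes, by Fisher's exact test with Bonferroni adjustment and by a z score within 20 classes of 3′ UTR length. These steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. The table holds gene-level values, so exon use and intron retention were not analysed here.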

Results

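SF3B6 encodes a small subunit of SF3b, the part of the U2 snRNP that binds the branch point of introns during splicing. Poly(A) RNA-seq compared SNU449 liver cancer cells 48 h after transfection of an siRNA against SF3B6 (3 libraries) with cells given a scrambled siRNA (3 libraries). The comparison addresses which mRNAs change when a splicing factor studied for its role in hepatocellular carcinoma is depleted. Values are the authors' normalized estimated counts, given as mean ± SD over 3 libraries per group. Normalized totals were 12.48 to 12.52 M in the knockdown libraries and 11.85 to 11.88 M in the controls. Every knockdown total thus lay above every control total (2-sided exact permutation p = 0.1, the smallest possible). The depth in reads is unknown.

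The targeted mRNA was almost lost. SF3B6, ENSG00000115128.6, lies on the minus strand of chromosome 2 from 24067584 to 24076443 in hg38 and has 4 exons. Its normalized counts were 9.19, 15.4 and 30.7 in the knockdown libraries and 596, 567 and 581 in the controls. The means were 18.4 ± 11.1 and 581 ± 14.8 (SD, n = 3 each), so 3.17% of the control level remained. The log2 fold change was -5.06 with a standard error of 0.34 (limma, adjusted p = 9.99e-06). All 3 knockdown libraries lay below all 3 controls, and the 2-sided exact permutation p was 0.1, the smallest that 3 against 3 allows.

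**Figure D1:**
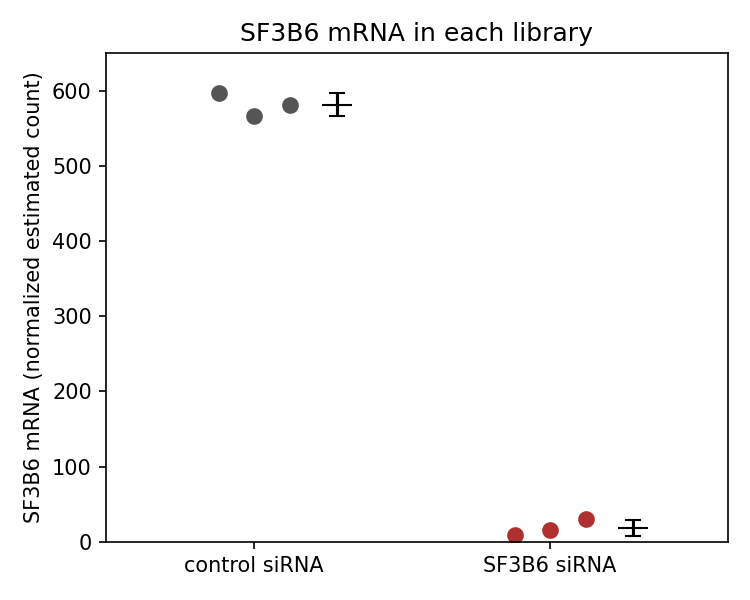
SF3B6 mRNA in normalized estimated counts for each of the 6 libraries (points), with the group mean and SD (bars) beside them. The controls lie between 567 and 596 and the knockdown libraries between 9.19 and 30.7.

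Knockdown changed 4554 of the 12135 genes tested (37.5%): 2285 were higher and 2269 lower (limma, adjusted p under 0.05). Most changes were small. At 2-fold or more, 48 genes rose and 314 fell, SF3B6 among them, but 96 rose and 196 fell after quantile normalization, 36 and 412 with the same total and 28 and 218 with a pseudocount of 10. The groups did not overlap in 6056 genes (49.9%), where chance gives 10%. The split depended on scaling: with every library set to the same total, 1536 genes were higher and 2883 lower, or 34.8% higher against 50.2%.

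Among genes with a mean of at least 100 and groups that did not overlap, the largest rises were in SLC2A3, RPL22L1, ZNF132, ADM, ELF3 and AMOTL2. SLC2A3, which encodes the glucose transporter GLUT3, rose from 407 ± 35.6 to 1109 ± 89.5, a log2 fold change of 1.44 (SE 0.09, limma adjusted p = 8.88e-06). RPL22L1, a paralog of the ribosomal protein gene RPL22, rose from 286 ± 25.5 to 771 ± 41.4 (log2 1.43). ADM, which encodes the vasodilator peptide adrenomedullin, rose by 1.36 on the log2 scale, ZNF132 by 1.42, the epithelial transcription factor ELF3 by 1.35 and AMOTL2, an angiomotin family member, by 1.27.

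By the same rule, and SF3B6 aside, the largest falls included SYTL4, KDELR2, CORO2B, RAB15 and TNFAIP8. KDELR2, a receptor that returns proteins to the endoplasmic reticulum, fell from 3280 ± 94.3 to 650 ± 53.4, a log2 fold change of -2.34 (SE 0.07, limma adjusted p = 9.70e-08). The log2 fold change was -2.24 for CORO2B, -2.12 for RAB15 and -1.92 for TNFAIP8. The 3′ UTRs of KDELR2, CORO2B, RAB15 and TNFAIP8 (1829 to 6307 bases) carry at least 1 of the heptamers ACAAAGA and CACAAAG. Both heptamers are also present in SF3B6 mRNA, and the 3′ UTR of SYTL4 carries neither. Of tested genes with a searched 3′ UTR, 21.2% carry at least 1, as do 46% of those that fell at least 2-fold. The median 3′ UTR of tested genes was 1124 bases. The size of the SYTL4 fall depended on 1 control library, with 56.4, 73.4 and 822 in the controls and 19.5 to 36.2 after knockdown; its log2 fold change of -2.49 became -1.27 without control replicate 3, where it still passed (adjusted p = 0.0203). Its call was lost when any 1 knockdown library was left out (adjusted p 0.053 to 0.0976), after quantile normalization (0.0643), without a variance trend (0.116), with robust variances (0.105) and with no filter on the mean (0.0554).

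The partners of SF3B6 in the SF3b complex all rose. SF3B1, the subunit that holds the branch point and the target of SF3b inhibitors, went from 5071 ± 344 to 7263 ± 478 (log2 0.52), SF3B3 rose by 0.48, SF3B5 by 0.53, SF3B2 by 0.33, SF3B4 by 0.35 and PHF5A by 0.35. All 6 passed the gene test, and all 6 passed adjusted over the list alone. The list was called higher by camera (adjusted p = 0.00011) with adjusted p = 0.106 with an estimated correlation.

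Other spliceosome genes moved less uniformly. Of 35 Sm, U1 and U4/U6.U5 proteins, 12 rose and 0 fell, 11 of them adjusted over the list alone, with PRPF3 up by 0.67, PRPF4 by 0.48, PRPF6 by 0.45 and PRPF8 by 0.44 (camera adjusted p = 0.0002; adjusted p = 0.106 with an estimated correlation). Among 19 U2 snRNP and 3′ splice site factors, 8 rose, including SF1 (0.54), which binds the branch point first, CHERP (0.57), U2AF2 (0.40) and PUF60 (0.39), while SF3A3 and DDX46 fell. The same 8 and 2 passed adjusted over the list alone, and the list missed the threshold (camera adjusted p = 0.0838; 0.0486 without knockdown replicate 3 and 0.0453 with no filter on the mean); 4 fell with the same total and 1 without control replicate 1 or without a variance trend. Of 11 minor spliceosome proteins, PDCD7 (0.49) and ZCRB1 (0.43) rose, with the same count of 2 adjusted over the list alone (camera adjusted p = 0.221). ZCRB1 lost its call when knockdown replicate 3 (log2 0.31), control replicate 2 (0.36) or control replicate 3 (0.42) was left out, and without a variance trend (0.43, adjusted p = 0.058).

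Splicing regulators split into risers and fallers. In the list of SR proteins and CLK kinases, 12 of 21 genes rose and 2 fell, with the same counts adjusted over the list alone. SRSF3 rose by 0.43 and SRRM1 by 0.58, whereas SRSF5 went from 1477 ± 66.6 to 876 ± 53.7 (log2 -0.75) and SRSF4 fell by 0.57. The list was called higher (camera adjusted p = 0.00403; adjusted p = 0.139 with an estimated correlation), while 7 rose after quantile normalization and 4 fell without knockdown replicate 3. Of 26 hnRNP genes, 16 rose, including HNRNPL (0.53), HNRNPH2 (0.51) and HNRNPA1 (0.41), and PTBP3 (-0.72), HNRNPUL2, HNRNPH1 and HNRNPU fell; adjusted over the list alone, 19 rose and 4 fell (camera adjusted p = 0.000228; adjusted p = 0.285 with an estimated correlation). Of 15 nonsense-mediated decay factors, 5 rose, among them SMG8 (0.49), MAGOH (0.44), EIF4A3 (0.28) and RBM8A (0.23), and SMG1 and SMG5 fell, the same 5 and 2 adjusted over the list alone, and the list was not called (camera adjusted p = 0.391); without a variance trend 3 were higher and 0 lower and EIF4A3 missed the threshold (adjusted p = 0.0511), and 1 fell without knockdown replicate 3 or control replicate 2. TAF1D, the only member of the snoRNA host gene list found in the table, rose by 0.73 and passed adjusted over the list alone.

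Ribosomal protein mRNAs of the list fixed beforehand rose almost without exception. Of 54 genes, 53 rose and 0 fell, and 53 passed adjusted over the list alone; RPS27L was the exception. RPL13A went from 15820 ± 590 to 23060 ± 415 (log2 0.54) and RPL19 rose by 0.44, and the median was 0.39 (camera adjusted p = 1.04e-28; adjusted p = 0.106 with an estimated correlation). Their share of all normalized counts was 4.24% ± 0.12 after knockdown and 3.41% ± 0.05 in controls. Ribosome biogenesis genes that MYC activates moved with them: 21 of 27 rose and 0 fell, and adjusted over the list alone 21 rose and 1 fell. NCL, which encodes nucleolin, rose by 0.45, NOLC1 by 0.52, PES1 by 0.57 and MYC itself by 0.55 (camera adjusted p = 3.28e-09; adjusted p = 0.106 with an estimated correlation).

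Many cell cycle and homologous recombination genes fell, and none of these lists held a gene that rose. Of 39 G1/S and DNA replication genes, 22 fell and 0 rose, or 25 adjusted over the list alone, with a median of -0.23. GINS1, part of the replicative helicase, went from 897 ± 42.4 to 387 ± 16.0 (log2 -1.21), with RFC4 at -0.90, E2F1 at -0.76 and the flap endonuclease gene FEN1 at -0.68 (camera adjusted p = 3.62e-05; adjusted p = 0.106 with an estimated correlation). Of 43 G2/M and mitosis genes, 17 fell and 0 rose, also 17 adjusted over the list alone, including ANLN (-0.93), the kinesin gene KIF11 (-0.69), MKI67 (-0.49) and TOP2A (-0.47) (camera adjusted p = 0.000502; adjusted p = 0.285 with an estimated correlation). In homologous recombination and the Fanconi anemia pathway, 15 of 32 genes fell and 0 rose, or 16 adjusted over the list alone. FANCD2 went from 676 ± 43 to 340 ± 73.8, and the log2 fold change was -0.93 for FANCL, -0.86 for BRCA2 and -0.79 for the helicase gene BRIP1 (camera adjusted p = 0.000531; adjusted p = 0.106 with an estimated correlation).

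p53 target genes went both ways. Of 27, PLK2 rose from 5429 ± 153 to 12560 ± 35.7 (log2 1.21), GADD45A by 0.71, and PLK3, TNFRSF10B and GDF15 also rose, while 6 fell, among them DDB2 (-1.38), POLH (-1.02) and the cell cycle inhibitor CDKN1A (-0.64). Adjusted over the list alone 5 rose and 7 fell, the median was 0.08 and the mean -0.06, and the list was not called (camera adjusted p = 0.766). The median was -0.04 without knockdown replicate 1 and 0.01 with the same total, where 3 were higher and 8 lower, and after quantile normalization 8 were higher and 5 lower. BCL2 family genes were also mixed in 15 tested: MCL1 (-0.50) and BOK (-0.73) fell, and BMF (0.55), BCL2L1 (0.25) and BID rose, the same 3 and 2 adjusted over the list alone. The median was -0.04 and the mean 0.02, with camera adjusted p = 0.923, and the median lay above 0 without knockdown replicate 1 (0.01), control replicate 1 (0.003) or control replicate 3 (0.04).

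NF-kB and cytokine genes rose in 11 of 19 cases and fell in 0, the same 11 adjusted over the list alone. NFKBIA, the NF-kB inhibitor and target, went from 558 ± 37.9 to 1151 ± 18.3 (log2 1.05), the interleukin 8 gene CXCL8 rose by 0.81, CSF1 by 0.80 and SOD2 by 0.56 (camera adjusted p = 0.000101; adjusted p = 0.217 with an estimated correlation). Interferon-stimulated genes did not move as a group: of 25, IFIT2 (0.75), IFIT3, IFIT5 and OASL rose and 4 fell, among them OAS3 (-0.76), OAS1 and IFIH1; adjusted over the list alone 3 rose and 4 fell. OASL was listed at 1.48 ± 0.78 in controls and at 27.6 ± 5.64 after knockdown. The median was -0.04, the mean 0.11 and camera adjusted p = 0.945. After quantile normalization 7 rose and the median was 0.14, and it was 0.003 without knockdown replicate 2 and 0.001 without control replicate 3.

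Among stress genes, 11 of 29 integrated stress response genes rose, with SLC7A5, an amino acid transporter gene, up from 7146 ± 181 to 14390 ± 607 (2.01-fold), DDIT4 by 0.96, SLC3A2 by 0.65 and WARS1 by 0.32; CEBPB, TRIB3 and CEBPG fell. Adjusted over the list alone 12 rose and 3 fell (camera adjusted p = 0.0258; adjusted p = 0.339 with an estimated correlation), and the call was lost without control replicate 3 (camera adjusted p = 0.0735) and with a mean of at least 50 (0.0768); with the same total 8 were higher and 6 lower. Heat shock and cytosolic chaperone genes rose in 10 of 18 cases, with HSP90AB1 up by 0.33, BAG3 by 0.55, HSPD1 by 0.41 and AHSA1 by 0.50, and DNAJA1 fell; the same 10 and 1 passed adjusted over the list alone (camera adjusted p = 0.000169; adjusted p = 0.109 with an estimated correlation). Endoplasmic reticulum chaperone genes were mixed, 7 up and 3 down of 21, or 8 and 4 adjusted over the list alone: DNAJB9 (0.87), HSP90B1 (0.29) and CANX (0.21) rose, the last 2 not after quantile normalization (0.07 and 0.01), and EDEM1 (-0.93), SDF2L1 and DNAJC3 fell (camera adjusted p = 0.221). After quantile normalization 2 were higher and 5 lower, with the same total 5 and 6, and without a variance trend 4 and 3.

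Cholesterol synthesis genes rose in 12 of 24 cases and fell in STARD4 (from 620 ± 25.9 to 311 ± 31.6) and EBP; adjusted over the list alone 12 rose and 3 fell. The count that fell was 4 without control replicate 1 and 1 without knockdown replicate 2, control replicate 2 or control replicate 3. HMGCS1, which makes HMG-CoA for sterol synthesis, rose from 1572 ± 24.6 to 3063 ± 60.8 (log2 0.96), MSMO1 rose by 0.83 and SQLE by 0.46 (camera adjusted p = 0.00442; adjusted p = 0.329 with an estimated correlation). Of 28 hypoxia and glycolysis genes, 8 rose and 6 fell, also adjusted over the list alone, with SLC2A3 and ADM up and LOX (-1.41) and ENO2 (-0.57) down, a median of 0.04 that became -0.03 after quantile normalization, and camera adjusted p = 0.315. After quantile normalization 2 were higher and 9 lower, with the same total 5 and 6, and without a variance trend 2 and 3, and the lower count was 3 without knockdown replicate 3 or control replicate 3. Mesenchymal and matrix genes rose in 13 of 30 cases, with THBS1 up by 0.59, CCN1 by 0.54, CCN2 by 0.56 and TAGLN by 0.48, and MMP1, ACTA2, MMP14 and VIM fell, a count of 4 that was 2 without knockdown replicate 1, knockdown replicate 3, control replicate 2 or control replicate 3; adjusted over the list alone 15 rose and 5 fell (camera adjusted p = 0.0123; adjusted p = 0.329 with an estimated correlation). Of 13 Wnt target genes, MYC, CD44 (0.35), MMP7, TBX3 and ZNRF3 rose and 3 fell: CCND1, which encodes cyclin D1, went from 5838 ± 459 to 2589 ± 165 (log2 -1.17), with GLUL (-0.77) and DKK1. The same 5 and 3 passed adjusted over the list alone, and the list was not called (camera adjusted p = 0.497). Without control replicate 1 or 2 the count of higher genes was 2, and without any 1 knockdown library, with the same total or upper quartile, or without a variance trend it was 3.

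**Figure D2:**
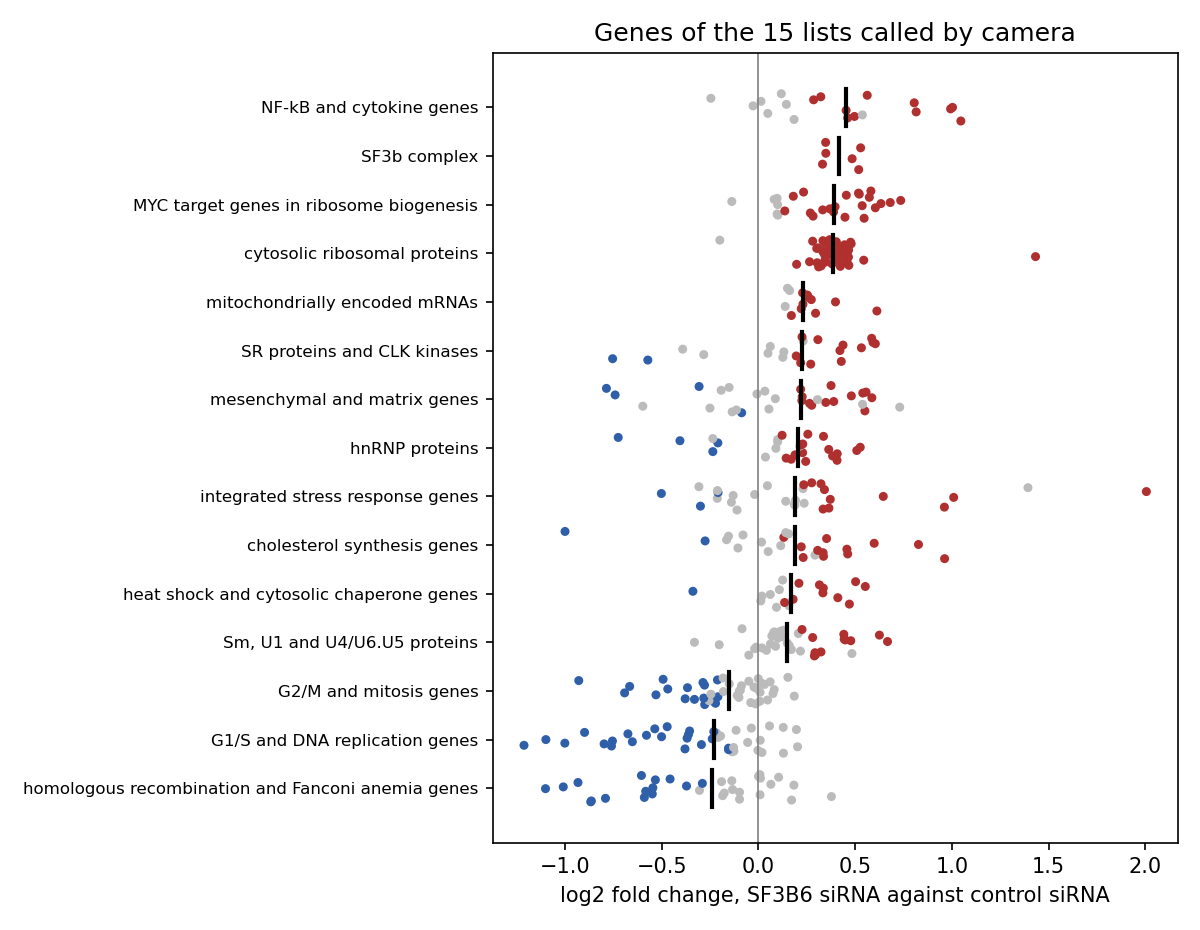
Log2 fold change (x axis) of each tested gene in the 15 lists called by camera; red points rose and blue points fell in the gene test, grey points did not pass, and black bars are medians. Medians run from -0.24 in homologous recombination and Fanconi anemia genes to 0.45 in NF-kB and cytokine genes.

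Mitochondrially encoded mRNAs rose in 10 of 13 cases, 11 adjusted over the list alone, with MT-CO1, the most abundant, up by 0.27 (camera adjusted p = 8.40e-05; adjusted p = 0.329 with an estimated correlation). The count was 3 after quantile normalization, 6 with the same total and 5 without a variance trend. None of 14 replication-dependent histone genes passed, also none adjusted over the list alone (camera adjusted p = 0.732); H2BC12, the most abundant, was at 68.0 ± 7.49 after knockdown and 62.1 ± 4.62 in controls. Hepatocyte markers were mostly low, with 17 of 24 under a mean of 10. ALB, among these, was at 0 after knockdown and 1.83 ± 2.29 in controls and was not tested. Of 7 tested, AMBP rose, and FGB, the most abundant, was at 2029 ± 251 after knockdown and 2431 ± 293 in controls. Of 16 immune markers, CD68 was tested, at 92.8 after knockdown and 107 in controls without passing, and none of 12 endothelial and red cell markers reached a mean of 10, the highest being CDH5 at 1.04. Of 7 epithelial markers tested, KRT7 and KRT8 rose, and KRT18, the most abundant, was at 2680 ± 82.9 and 2709 ± 74.4. These counts were the same adjusted over the list alone.

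Abundant genes tended to rise (Spearman rho across genes 0.278 between log2 fold change and mean, with genes not independent replicates), so lists were also set beside random lists matched on transcript length, GC content, intron number, span and mean. Of 14 called lists so compared, 7 had a median in the upper 2.5% of the matched lists and 3 in the lower 2.5%, while the Sm, U1 and U4/U6.U5, hnRNP, heat shock and cholesterol lists lay within. The Wnt and minor spliceosome lists, which were not called, also lay in the upper 2.5% (percentiles 99.85 and 98.39). Among genes without either heptamer, the SF3b, SR and homologous recombination lists lay within the range of their matched lists (percentiles 91.15, 96.44 and 7.85). The SR excess over matched lists did not shrink, at 0.156 with all members and 0.157 without heptamer carriers. For SF3b, which lost SF3B1 alone, the excess went from 0.215 to 0.095, and for homologous recombination from -0.18 to -0.136. Quantile normalization ended the camera calls of the SR, hnRNP, integrated stress response, heat shock, cholesterol, mesenchymal and mitochondrial lists. Their medians went from 0.23 to 0.13 (SR), 0.20 to 0.08 (hnRNP), 0.17 to 0.09 (heat shock), 0.22 to 0.14 (mesenchymal) and 0.23 to 0.07 (mitochondrial), while those of the integrated stress response (0.19 and 0.19) and cholesterol (0.19 and 0.18) lists moved little. It also shrank rises that stayed past the threshold, to log2 values of 0.33 for RPL13A, 0.28 for RPL19, 0.20 for NCL, 0.16 for HNRNPA1, 0.15 for HSPD1, 0.09 for HSP90AB1, 0.37 for THBS1 and 0.22 for CD44, with a ribosomal protein median of 0.25.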

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

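The genes without either heptamer were chosen as an alternative after the data were seen, as was the count of other splits as a test. Direction and side of the threshold held in 1630 of 1647 comparisons of named genes and 405 of 423 of gene lists; a call was lost in 14 comparisons of genes and 9 of lists and gained in 3 and 2. Counts of higher and lower genes were 1307 and 1273 at adjusted p under 0.01 and 48 and 314 at 2-fold or more (96 and 196 after quantile normalization). Camera called 8 lists after quantile normalization, against 15, and 0 with an estimated correlation, where 8 of 25 had an unadjusted p under 0.05; fry, which tests each list against no change, called 20. With an estimated correlation, calls were lost also where that correlation lay under the preset 0.01. It was -0.0027 for G1/S, -0.0011 for homologous recombination and 0.0017 for Sm, U1 and U4/U6.U5 genes. A higher correlation than the preset therefore does not account for the lost calls of these lists. It lay above the preset in other called lists, such as ribosomal proteins (0.2937). The cause was not tested further. Camera's direction turned for lists that were not called, whatever the sign of the median: BCL2 family and interferon genes with a mean of at least 50 (medians -0.083 and -0.039), endoplasmic reticulum chaperone and hypoxia genes after quantile normalization (-0.01 and -0.033), interferon genes without knockdown replicate 3 (-0.048; leave-one-out range -0.081 to 0.003), and p53 and BCL2 family genes among genes without the heptamers (0.056 and -0.129). Leaving out each library in turn gave 1806 to 1957 genes higher, 1755 to 1951 lower, 14 to 16 lists and an SF3B6 log2 fold change of -5.49 to -4.67. Genes without either heptamer gave 1937 higher and 1546 lower of 9354. The replicate block gave 2191 and 2196 and kept 92% of calls. Same-numbered libraries deviated with correlations of -0.02, 0.01 and 0.02, and not every library correlated best with its own number. No pairing by number was visible, but 3 libraries per group cannot exclude one, and the labels do not say. The edgeR and DESeq2 alternatives were not run, since whole reads could not be recovered. Of the 10 splits of 6 libraries the real one, counted as 1 in each direction, gave 2285 and 2269 genes and the highest other 0; 10 splits are too few for a share under 0.05. The depth in reads is unknown; low values limit genes such as OASL, whose log2 fold change was 3.56, or 1.70 with a pseudocount of 10.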

Other observations

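Gene families named by a shared symbol stem were compared after the data were seen, 70 families with at least 15 tested genes. Symbols in which letters and a further number follow the first number, such as EIF4A3, fell outside the stem rule. A family such as EIF or COX therefore leaves out members with such symbols. Beside the ribosomal protein families RPL (43 higher and 1 lower of 47) and RPS (30 and 0 of 32), 9 families passed (limma camera). Of these, 17 of 27 EIF genes rose and 1 fell (adjusted p = 8.36e-06), 21 of 49 MRPL genes, which encode mitochondrial ribosomal proteins, rose and 2 fell (adjusted p = 0.00547), and 8 of 15 COX genes rose (adjusted p = 0.012). Of 34 DDX genes 17 rose and 4 fell (adjusted p = 0.0426), of 31 POLR genes 12 and 3 (0.0463), and 7 rose in each of the TIMM (16 tested) and DHX (15 tested) families (0.0498 each). Of 21 STK kinase genes 8 fell and 1 rose (adjusted p = 0.0122), and of 103 FAM genes, which share a name and no function, 35 fell and 8 rose (adjusted p = 0.0122). The MRPS family, also of mitochondrial ribosomal proteins, did not pass, with 6 of 29 higher (adjusted p = 0.276). With the same total the higher and lower counts were 12 and 3 for MRPL, 5 and 0 for COX, 9 and 6 for DDX, 8 and 3 for POLR, 3 and 0 for TIMM, 5 and 0 for DHX, 1 and 12 for STK and 4 and 42 for FAM. Under each of the 3 other scalings the medians kept their sign, but the DDX, POLR, TIMM and DHX families missed the threshold (adjusted p 0.0534 to 0.324), as did FAM after quantile normalization (0.0973). With an estimated correlation the smallest adjusted p of the passing families was 0.276.

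In the 3 patterns below, the tests of genes with a mean of at least 500, genes without any of 14 heptamers, gene span, intron number and span with mean, and falls among homologous recombination genes without heptamers were chosen after the results were seen, and the seed test of the falling lists was divided by list after its result, with its limits unchanged; the other tests of these patterns were fixed before their results.

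More genes fell than rose at 2-fold or more (314 and 48, but 196 and 96 after quantile normalization, 412 and 36 with the same total and 218 and 28 with a pseudocount of 10), and part of this may come from an siRNA that acts on other mRNAs through seed matches, the short 3′ UTR sites that an siRNA can pair with as a microRNA does. ACAAAGA led all heptamers in the 3′ UTRs of fallen genes, in 109 of 300 against 55.9 expected from 3′ UTR length (z 8.69). CACAAAG came second (z 8.55), overlapping it at positions 520 to 527 of SF3B6 mRNA. They lie in the coding part of exon 4 (chromosome 2, 24067827 to 24067834, hg38, minus strand). GCTATGT, absent from SF3B6 mRNA, came next (61 genes, z 5.89). Fisher's exact test, which took no account of 3′ UTR length, gave Bonferroni p = 6.15e-17 for ACAAAGA and 1.48e-07 for GCTATGT. By Fisher's test 99 heptamers passed, 14 of them in SF3B6 mRNA, which holds 4.49% of all heptamers. Its heptamers were thus over-represented among those that passed, but most that passed were absent from it, so passing alone did not mark the target. Overlapping heptamers are not independent, and the over-representation was not tested. Fallen genes had longer 3′ UTRs (median 1627 bases against 1124 in tested genes), and z was as low as 1.94 (TTTTTAA) among heptamers that passed. Among genes that fell by less than 2-fold, which the search counted in its background, ACAAAGA or CACAAAG was more frequent than among risen genes (30.3% against 15.4%, odds ratio 2.39, or 2.06 within classes of 3′ UTR length, whose medians were 1454 and 981.5 bases). Among genes not past the test the share was 19.6% (median 3′ UTR 1062 bases), and no odds ratio was computed against them. ACAAAGA and CACAAAG do not account for the whole excess of falls, since 162 genes without either fell and 38 rose (exact binomial p = 1.98e-19). Among genes without any of the 14 heptamers of SF3B6 mRNA that passed, 27 fell and 8 rose (exact binomial p = 0.00188), while other seeds stay open. Noise of low values is argued against by 53 falls and 12 rises at a mean of at least 500 (exact binomial p = 2.79e-07). The binomial tests took genes as independent, which they are not, and were run under the authors' scaling only. A long gene span stays a possible explanation (median 40890 bases in fallen genes against 23980 in lists matched on mean, percentile 100), and intron number stays open (median 7 in both, percentile 59.7).

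Ribosomal protein mRNAs rose together. Transcript length and GC content are argued against as the whole explanation. The list's median of 0.39 exceeded that of lists matched on mean and each of these by 0.20 and 0.21 (log2), at percentile 100. The matched lists themselves had medians of 0.19 and 0.17, so part of the rise was shared by genes of like features and mean. Few introns or a short span are argued against as the whole by the excess over lists matched on these. It was 0.32 without mean (matched median 0.07) and 0.126 with mean (matched median 0.26). Scaling is argued against by 48 of 54 genes still called higher under the least favourable of 3 other scalings. With all features matched the excess was 0.14 over a matched median of 0.24, with a gap of up to 0.22 SD left in the matching. A response to the loss of SF3B6 remains a hypothesis, which a second siRNA would test.

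G1/S and homologous recombination genes fell together, for which slower growth after SF3B6 loss was not tested. Intron number and span (matched without mean), transcript length and GC content (each with mean) are argued against as the whole cause. Both lists lay at or below percentiles of 0.38, 1.19 and 0.12 of lists matched on these, in that order. Lists matched to the homologous recombination genes on transcript length and mean had a median of -0.09 against -0.24. Part of that fall may thus be shared by genes of like length and mean. Matches to ACAAAGA and CACAAAG in the members' own 3′ UTRs are argued against as the whole cause for the G1/S list. Its 35 members without either heptamer lay at percentile 0. For the homologous recombination list such matches stay a possible explanation of part. The median of its 28 members without either heptamer (-0.19) lay at percentile 7.85, within the range of matched lists. As the whole cause they are argued against there, since 12 of these 28 fell, FANCD2, FANCL and BRIP1 among them. Of other genes without heptamers 16.0% fell (Fisher's exact test, p = 0.00071). That test matched no feature and took genes as independent. Other seeds, and effects through other fallen genes that carry a heptamer, such as CCND1, were not tested for either list.

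Single-exon genes, 190 in number, had a median log2 fold change of 0.08, which was 0.19 above multi-exon genes matched on mean (percentile 100), 0.16 above those matched on length, GC content and mean (percentile 100) and 0.07 above those matched on span and mean (percentile 98.1). Across genes, intron number had a partial rank coefficient of 0.0151 (SE 0.0115) with length, span, GC content and mean held by a rank regression over 11982 genes, less than 2 SE from 0, so its sign was not determined. The coefficient of span in the same regression was -0.156 (SE 0.0127). No heptamer of the risen genes met the limits set on both z and the Bonferroni p for a seed of the control siRNA. The largest z was 4.58, for GGTTTGT (335 genes against 275 expected from 3′ UTR length, Fisher's exact test, Bonferroni p = 1). Fisher's test took no account of 3′ UTR length, which was shorter in risen genes (median 981.5 bases against 1124 in tested genes). A seed of the control siRNA was therefore not ruled out.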
